A study of Mus musculus with 8 samples.

How the data were processed

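Myocardium samples labelled NPRA-/- (n = 5) and NPRA+/+ (n = 3) were profiled on single-colour arrays of 15712 spots. Per the labels' protocols, tissue was kept in RNAlater and frozen, total RNA was extracted with Trizol, and the RNA was amplified with random primers and labelled with Cy3. The authors scanned each array with Agilent Feature Extraction 11.0.1.1, per the file headers and the submitters' processing notes. The deposited intensity values are, per the file headers, a processed signal for each spot (background-subtracted and detrended over the array, not scaled between arrays) and the raw median brightness of the spot and of its local background. The deposited columns marking spots well above background, saturated, non-uniform or outlying (other units, coded as yes or no) were used as filters. A further table holds log2 values that the authors deposited for 14236 circRNA probes. Set against the scanner values, each of its columns correlated at 0.999 or above with the log2 raw median brightness of its array and at 0.955 to 0.963 with the log2 processed signal, so it was read as log2 without background subtraction. Its column medians were 5.84 (217), 5.84 (227), 5.84 (231), 5.86 (240), 5.85 (241), 5.84 (228), 5.84 (230) and 5.85 (242), so it had been normalized between arrays, by a method not given in the sources used here; probes were not centred, and only the method stayed unknown.

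Spots marked as non-uniform or as population outliers were removed, and repeated spots of a probe were averaged on the log2 scale. From each log2 processed signal the 75th percentile of its array over all non-control probes was subtracted. Of 14236 circRNA probes, 1209 were left out because they were well above background on fewer than 3 of the 8 arrays, and 12 because fewer than 2 arrays of a genotype had an unmarked spot, which left 13015. Principal components, correlations and counts of probes without overlap used the 12990 of these with a value on all arrays. Of the circRNA probes, 11799 were well above background on all 8 arrays. On 71 non-control probes with 10 spots each, the median SD between spots of an array was 0.05 on the log2 scale.

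Genotypes came from the labels. They were compared with lmFit and eBayes of limma 3.58.1 in R 4.3.3, 2-sided, with NPRA-/- minus NPRA+/+ as the direction, all 8 arrays in the fit and no covariate. P-values were adjusted with the Benjamini-Hochberg method over all 13015 probes, and probes were counted at an adjusted p of 0.05 and at an unadjusted p of 0.05 with at least 1.5-fold. Control and repeated probes were fitted and adjusted apart from these. Single measures per array were compared with exact permutation tests over the 56 splits of 8 arrays into 5 and 3, whose smallest p is 0.018. In data simulated for this comparison with 12990 probes, independent noise and 200 changed probes, the fit recovered 23.5% of 1.5-fold, 74.5% of 2-fold and 92.5% of 4-fold changes at an adjusted p of 0.05, with 3, 8 and 4 false calls. In the measured data the first principal component held 61.9% of the variance. Probes there did not vary independently, so these rates need not hold for the measured data.

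The genotype comparison, its scaling, filter on dim probes and thresholds, and the tests of distance and array quality were chosen before the data were examined. So was the rule for the probes named: those past the adjusted p with the widest difference, filled up in order of p, 12 in each direction, and well above background on all arrays of the genotype with the higher mean. The test of the first principal component was not part of that plan. Nor were the counts of probes without overlap, by signal level, detected in only 1 genotype, or among control probes. Because probes are not paired with genes here, 2 in each direction are given. For the same reason the 16 planned lists of host genes and the circRNAs of the Npr1 locus were not analysed here: 0 circRNA probe IDs matched the table of mouse genes at hand. The positions of the arrays fill 1 slide layout of 2 rows and 4 columns; one row held NPRA-/- samples 217, 227, 231 and 240, and the other held NPRA-/- sample 241 and all NPRA+/+ samples. Sample 240 came from a separate scan, and the slide of each array is not given in the sources used here, so that it could have been on another slide, and row and column then compare positions and not places on 1 slide.

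Alternatives were normexp background correction with an offset of 50 (on the raw median brightness, since the files used here hold no mean brightness), quantile normalization, a percentile over probes well above background on all arrays, no filter and a stricter filter on dim probes, the deposited log2 table, limma-trend with robust eBayes, array weights, slide row and slide column as covariates, other thresholds, and each array left out. The slide row with both genotypes alone and scan as a covariate (the same fit as leaving out sample 240) were added after seeing the data.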

Results

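Circular RNAs (circRNAs), closed RNA loops formed by back-splicing, were measured in the myocardium of mice with a cardiac-specific deficiency of NPRA (NPRA-/-, n = 5) and of normal mice (NPRA+/+, n = 3), all on the C57BL/6 background. NPRA is the natriuretic peptide receptor A, the receptor guanylyl cyclase through which atrial and brain natriuretic peptides act on the heart and vessels. Each RNA sample was labelled with Cy3 and hybridised to 1 Arraystar mouse circRNA array with 14236 circRNA probes. The labels number the samples but do not state that each came from a separate animal, so p-values measure the spread between these samples. The share of circRNA probes well above background was 89.5% ± 2.0 (SD, n = 5) in NPRA-/- and 89.1% ± 1.97 (SD, n = 3) in NPRA+/+ (2-sided exact permutation p = 0.857). The raw 75th percentile of probe intensity was 110 ± 10.3 in NPRA-/- and 109 ± 10.9 in NPRA+/+ (2-sided exact permutation p = 0.875). The median local background was 14 on all arrays except NPRA-/- sample 240, where it was 13, and no spot was saturated. The number of arrays limits the precision of every comparison.

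The first comparison asked whether the circRNA profiles of NPRA-/- and NPRA+/+ myocardium differed as a whole. NPRA+/+ samples lay close together on the first principal component, at 28.2 (sample 228), 35.3 (sample 230) and 30.0 (sample 242), while NPRA-/- samples were spread from -42.2 to 17.4. NPRA-/- samples 217, 231 and 241 lay at -42.2, -41.0 and -32.1, and samples 227 and 240 lay at 4.41 and 17.4, between these and the NPRA+/+ samples. The component held 61.9% of the variance, and its mean was -18.7 ± 27.7 (SD, n = 5) in NPRA-/- and 31.2 ± 3.70 (SD, n = 3) in NPRA+/+ (2-sided exact permutation p = 0.0357, 0.179 after Benjamini-Hochberg adjustment over 5 array measures). The 5 include saturated spots, which were 0 on every array and could not give a small p. The adjusted value therefore depends on which measures were pooled. The mean correlation between samples, across probes, was 0.974 within NPRA-/- (10 pairs), 0.987 within NPRA+/+ (3 pairs) and 0.962 between the genotypes (15 pairs). The mean distance (1 minus the correlation) between genotypes exceeded that within genotypes by 0.0155 (1-sided exact permutation p = 0.0357, where 0.0179 is the smallest p that the 56 splits of the samples can give). Leaving out any 1 sample gave exact p-values from 0.0571 to 0.0952. The slide of each array is not given in the sources used here, so slide rows and columns stand for positions that may lie on more than 1 slide. One row of positions held NPRA-/- samples only; in the other row, NPRA-/- sample 241 (-32.1 on the component) met all 3 NPRA+/+ samples, the difference in distance was 0.0310, and its exact p of 0.25 is the smallest that 4 splits can give.

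**Figure D1:**
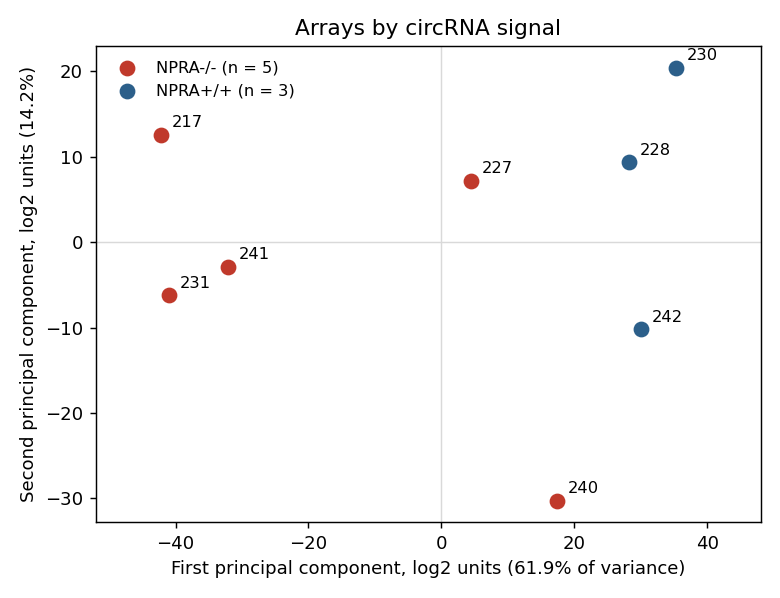
Each point is 1 array, placed by the first and second principal components of the log2 signal of 12990 circRNA probes, in log2 units, with the sample number beside it and the genotype in colour. NPRA+/+ samples lie between 28.2 and 35.3 on the first component, and NPRA-/- samples between -42.2 and 17.4.

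The second comparison asked which circRNAs differed in signal between NPRA-/- and NPRA+/+ myocardium. Among 13015 circRNA probes tested, 628 were higher and 857 were lower in NPRA-/- by at least 1.5-fold at an unadjusted p under 0.05, or 1485 probes in all (11.4% of those tested). At least 2-fold differences were found for 174 higher and 362 lower probes. None of them passed limma's test at a Benjamini-Hochberg adjusted p under 0.05, and the lowest adjusted p was 0.0787. Without the fold threshold, 3376 probes had an unadjusted p under 0.05 (1817 higher, 1559 lower), against 651 that chance would give on average. Probes vary together, and some other splits of the samples into 5 and 3 also gave counts far above 651. The highest were 5614, for samples 217, 231 and 241 against the rest, and 3123, for samples 240, 230 and 242 against the rest. Both share part of the genotype grouping, so a genotype effect would raise them too. Most other splits gave fewer than 651 probes, down to 91 for samples 227, 241 and 242 against the rest. The genotype count was 2135 without sample 230, 1978 with slide row and 1977 with slide column as a covariate, and 5416 with array weights. All 5 NPRA-/- samples lay on one side of all 3 NPRA+/+ samples for 2431 of 12990 probes (18.7%, with 1398 higher and 1033 lower). Chance gives 3.57% on average, with the same limit. Differences over all probes ranged from -3.10 to 3.49 on the log2 scale, with a median of 0.04 and a median standard error of 0.15. The median SD of a probe was 0.22 between NPRA-/- samples and 0.15 between NPRA+/+ samples.

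The call at an adjusted p of 0.05 rested on sample 240, the only array from a separate scan: without it, which is the same fit as scan as a covariate, 2504 probes passed (1292 higher, 1212 lower). The number without overlap of the genotypes was 4377 without sample 240 (chance 5.71%), and 2553 to 3539 without any other single sample (chance 5.71% or 9.52%). With slide row as a covariate, 0 probes passed the adjusted p and 1577 the unadjusted p with 1.5-fold; within the slide row that held both genotypes, these counts were 721 and 2337, but they set 1 NPRA-/- sample against 3 and assume that it varies like NPRA+/+ samples, although NPRA-/- samples varied more (0.22 against 0.15), so they do not test genotype within a row. With slide column as a covariate, 908 probes passed the unadjusted p with 1.5-fold, and array weights gave 3708 probes past the adjusted p.

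Among the probes well above background on all 8 arrays, ASCRP4000970 and ASCRP4012529 had the lowest p of those higher in NPRA-/-, and ASCRP4010946 and ASCRP4007126 the lowest p of those lower. The signal of ASCRP4000970, on the log2 scale relative to the 75th percentile of its array, was -1.03 ± 0.18 (SD, n = 5) in NPRA-/- and -1.84 ± 0.11 (SD, n = 3) in NPRA+/+, a difference of 0.81 ± 0.13 (SE) or 1.76-fold. That of ASCRP4012529 was 4.38 ± 0.15 in NPRA-/- and 3.63 ± 0.15 in NPRA+/+, a difference of 0.76 ± 0.12 (SE) or 1.69-fold. ASCRP4010946 had -2.93 ± 0.15 in NPRA-/- and -1.92 ± 0.19 in NPRA+/+, a difference of -1.01 ± 0.12 (SE), and NPRA+/+ signal was 2.02 times that of NPRA-/-. The widest of these differences was that of ASCRP4007126, at -2.75 ± 0.37 in NPRA-/- and -1.17 ± 0.22 in NPRA+/+, or -1.59 ± 0.22 (SE) and 3.0 times as much signal in NPRA+/+. For each of the 4 probes, all 5 NPRA-/- samples lay beyond all 3 NPRA+/+ samples, and limma's adjusted p of 0.0787 did not pass 0.05. The probes were picked by their p in these same samples. The lack of overlap thus follows in part from the choice, and the differences may be overstated. Of all circRNA probes with a value on every array, 18.7% had no overlap. Without sample 240 the adjusted p of each was 0.0167, and over all alternatives it ranged from 0.00427 to 0.293. With normexp background correction the differences were 0.35 for ASCRP4000970, 0.73 for ASCRP4012529, -0.28 for ASCRP4010946 and -0.53 for ASCRP4007126. With the deposited log2 table they were 0.56, 0.91, -0.49 and -0.88, in the same order. ASCRP4012529, the brightest of the 4, changed least, and the sizes of the others depended on how background was handled. The files do not pair probes with genes, so host genes, and circRNAs of Npr1 (the gene of NPRA) as a check of the knockout, were not analysed here.

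**Figure D2:**
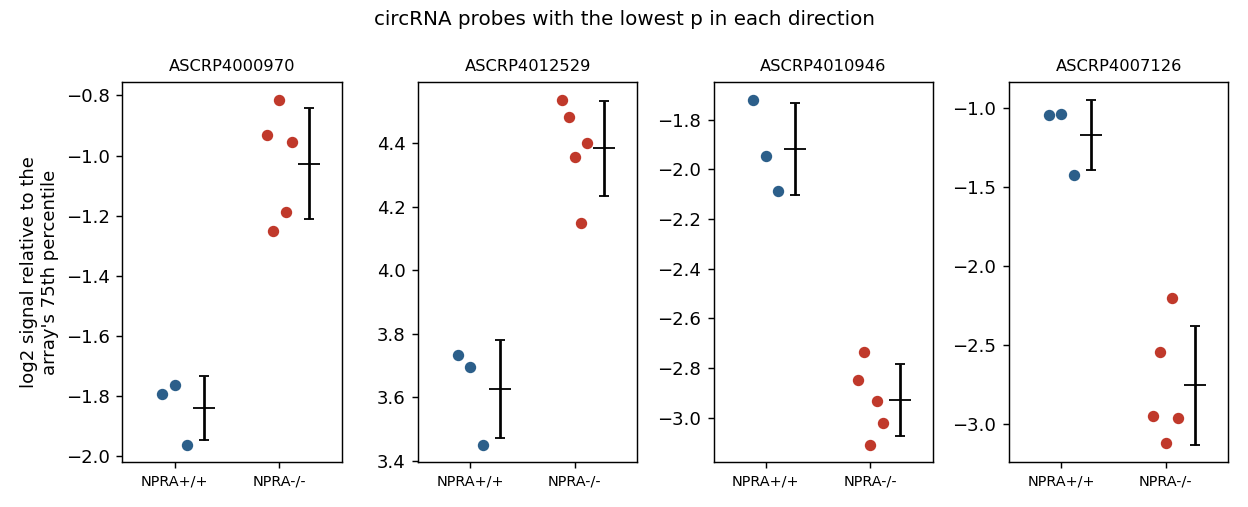
Points are the log2 signal of single samples relative to the 75th percentile of their array, for the 2 circRNA probes with the lowest p in each direction, with the mean and SD of each genotype beside them (n = 5 NPRA-/-, n = 3 NPRA+/+). The genotypes do not overlap in any of the 4 probes, with differences of 0.81, 0.76, -1.01 and -1.59. This follows in part from picking the probes by p in these same samples. The signal axes differ between panels and do not start at a common value.

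The balance of higher and lower differences varied with signal level, with no steady trend. In the fifth of the probes with the highest mean signal, 222 of the differences of at least 1.5-fold at an unadjusted p under 0.05 were lower and 131 higher (62.9% lower, 95% exact binomial interval 57.6 to 67.9, which treats probes as independent). From the fifth with the lowest mean signal upwards, the share lower was 47.5%, 62.9%, 60.2% and 54.1% in the other four. Over all probes of the fifth with the highest mean signal, the median difference was 0.01 on the log2 scale. The median of the brightest probes (the fifth with the highest mean signal) minus that of the other probes, per array, was -0.02 ± 0.06 (SD, n = 5) in NPRA-/- and 0.02 ± 0.05 (SD, n = 3) in NPRA+/+, a difference within the spread between samples (2-sided exact permutation p = 0.5). The share lower among the brightest probes was 53.5% with quantile normalization and 54.6% with the deposited log2 table. It was 54.1% without sample 228 and 57.3% without sample 230.

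Few circRNAs were detected in only one genotype. Of the 14236 probes, 6 were well above background on all 5 NPRA-/- arrays and on no NPRA+/+ array, and 5 on all 3 NPRA+/+ arrays and on no NPRA-/- array. Of the 56 splits of the samples into 5 and 3, 9 gave at least as many of the first kind and 11 of the second.

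Pooled over unlike classes, control probes and repeated probes separated the genotypes about as often as circRNA probes did. Of 111 control and repeated probes well above background on at least 3 arrays, 10 were higher in all NPRA-/- samples than in all NPRA+/+ samples and 9 were lower, where chance gives 1.98 for each; these are 17.1%, beside 18.7% of circRNA probes. Of the 19, 8 were among the probes marked as control (10 E1A and eQC and 24 others). The other 11 were among the larger set of repeated probes not marked as control (43 A_51_P, 15 CUST, 14 AS_circRNA_control and 5 MM9NEGATIVE). The pooled share thus covers classes that separated unequally often and does not describe any single class. The E1A and eQC probes separated the genotypes most often for their number, and the MM9NEGATIVE probes not at all. In a separate fit, adjusted over these 111 probes alone, none passed limma's adjusted p of 0.05, and 28 had an unadjusted p under 0.05. The E1A and eQC probes are made for spike-in RNA and have no intended mouse target; per the file headers the fit to a spike-in series had a slope of 0 on every array. Among them, (+)eQC-40 had a log2 signal of -0.94 ± 0.89 (SD, n = 5) in NPRA-/- and -2.68 ± 0.26 (SD, n = 3) in NPRA+/+, and (+)eQC-39 had -2.89 ± 1.06 and -0.54 ± 0.76, so that these probes differed in opposite directions (1.74 and -2.34, limma adjusted p = 0.0794 for both).

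**Figure D3:**
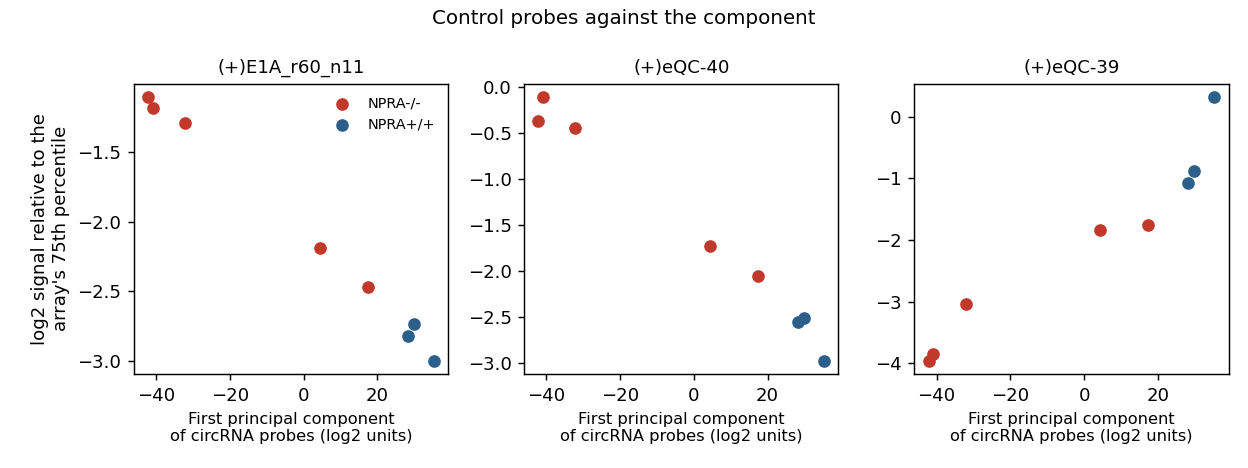
Each point is 1 array: the log2 signal of a control probe relative to the array's 75th percentile, against the first principal component of the circRNA probes in log2 units, with the genotype in colour. NPRA-/- samples were higher than NPRA+/+ samples in (+)E1A_r60_n11 and (+)eQC-40 and lower in (+)eQC-39, and samples 227 and 240 lay between the other NPRA-/- samples and the NPRA+/+ samples in all 3 panels.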

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

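The tests of slide row, swapped labels, control probes, separate scan and dim probes were chosen only after the results they bear on had been seen; counting over other splits of the samples was planned, but how its outcome would be read was written down after it was seen.

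The number of probes past an unadjusted p of 0.05 and 1.5-fold was 1485 for the genotypes. Of the 56 splits of the samples into 5 and 3, 2 gave as many, the real one included, which is under 5% of splits. This does not exclude chance, because the reading was set after the outcome and the splits ignore slide row. A split that mixed the genotypes, with samples 240, 230 and 242 against the rest, gave 1124. The highest count in another split was 2369. For the count at an adjusted p of 0.05, which was 0, all 56 splits give as many by definition, so the splits decide nothing; the highest other split gave 4104. That split set samples 217, 231 and 241 apart from the rest, as the first principal component did. It was picked as the highest of the 56 and also sets NPRA-/- samples against all NPRA+/+ samples. Its count therefore restates that grouping and is no separate evidence for it.

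NPRA-/- samples lay far apart on the first principal component, samples 227 and 240 nearest to NPRA+/+. Slide row is a position, as the slide of each array is not given in the sources used here. As the whole cause it is argued against, since 75.7% of the component's variance lay within rows. By the same measure, 39.9% lay within genotypes, so an equal genotype effect in all samples was not the whole cause either. Spread within groups forbids neither row nor genotype as a part of the cause. Swapped or wrong labels stay open: 0 NPRA+/+ arrays lay on the negative side, but an array exchanged with sample 227 or 240 would lie on the positive side too. Signal not tied to the probes' targets, such as a difference in labelling or hybridisation, may contribute but is left open, since the control classes differ: of the E1A and eQC probes, which have no intended mouse target, 6 of 10 (60%) had an absolute correlation above 0.9 with the component, against 6 of 43 A_51_P probes (2-sided Fisher's exact p = 0.00525) and 2353 of 12990 circRNA probes (18.1%, p = 0.00381, with probes taken as independent), but 0 of 5 MM9NEGATIVE, 0 of 15 CUST, 6 of 14 AS_circRNA_control (42.9%) and 4 of 24 other control probes (16.7%) did. Sample RNA binding to those probes could also follow a real change in RNA. Genotype as a part of the cause, and an unequal loss of NPRA among NPRA-/- samples, stay open, because no probe could be assigned to Npr1.

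Calls at an adjusted p of 0.05 appeared without sample 240 (2504 probes) or with array weights (3708, with the lowest weight, 0.299, on sample 240). Both called 2427 probes, and 2164 of the 2504 had an unadjusted p under 0.05 over all 8 samples. These fits share most arrays and the weights came from the same data, so the overlap is no separate evidence. Sample 240 was the NPRA-/- sample nearest to NPRA+/+ on the first principal component. Leaving it out or giving it less weight therefore parts the genotypes further on that component. Dim probes on sample 240 are argued against as the cause, since 0 of the 11799 probes well above background on all 8 arrays passed with it included. With genotype in the fit, 72 probes passed for scan, but the second scan held this sample alone, so that scan and sample cannot be told apart. A difference between NPRA-/- samples in the tissue itself was not tested.

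Sample 240 stood apart from the other NPRA-/- samples in the share of circRNA probes well above background (85.9%) and in its median local background (13, against 14 on the others). Of 11 measures examined, about 5% show such a gap by chance, but the background takes whole values, so any 1 array that differs by 1 stands apart and that rate does not hold for it. Outside the circRNA probes, 3 control probes were higher in all NPRA-/- samples than in all NPRA+/+ samples by at least 2-fold: (+)E1A_r60_n11 by 1.21, (+)eQC-40 by 1.74 and ETG05_36762 by 1.15 on the log2 scale, each with a limma adjusted p of 0.0794. In the other direction, (+)eQC-39, (+)eQC-42 and (+)eQC-41 were lower in all NPRA-/- samples (-2.34, -1.60 and -1.13 on the log2 scale, with the same adjusted p). The adjustment was over the 111 control and repeated probes.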

How the results depend on the processing

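The slide row with both genotypes alone and scan as a covariate were chosen after seeing the data. The count at an adjusted p of 0.05 was 0 in 16 of 21 alternatives, with lowest adjusted p from 0.0514 to 0.283. It was 3708 with array weights (1981 higher, 1727 lower), 721 in the slide row with both genotypes (324 higher, 397 lower; 1 NPRA-/- sample with the spread of NPRA+/+, so no test of genotype), 2504 with scan as a covariate (the same fit as leaving out sample 240), 1351 at an adjusted p under 0.1 (654 higher, 697 lower), and from 0 to 2504 with single samples left out, the latter without sample 240. The count at an unadjusted p of 0.05 with 1.5-fold, 1485, stayed within 1.5 times in 16 of 22 alternatives, and from 1191 to 2117 with single samples left out. It was 508 with normexp (166 higher, 342 lower; 67.3% lower against 57.7%), 735 with the deposited log2 table (307 and 428), 908 with slide column as a covariate (324 and 584), 2337 in the slide row with both genotypes (1114 and 1223), 3376 with no fold threshold and 536 at 2-fold. The offset in normexp and the absence of background subtraction in the deposited table shrink the folds of dim probes by construction; the cause of the other shifts was not tested. The excess distance between genotypes kept its direction throughout and its side of 0.05 in 6 of 15 alternatives; it was 0.0116 to 0.0256 with single samples left out, where fewer splits remain, and 0.0310 in the slide row with both genotypes. The differences in the share of probes well above background (0.33) and in the raw 75th percentile (1.23) lay within the spread between samples and changed sign when single samples were left out, over -0.42 to 1.45 and -3.68 to 7.13. The 4 named probes kept their direction in every alternative, which is likely for probes picked by their p in these samples. No paired analysis was possible because the genotypes share no replicate numbers. Slide as a block was not run, since the slide of each array is not given in the sources used here, and the host gene lists and their alternatives were not run. Signal over background limits what could be tested: 1209 dim probes were left out.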

Other observations

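NPRA-/- sample 227 correlated, across 12990 probes, at 0.983 to 0.986 with the NPRA+/+ samples. With the other NPRA-/- samples it correlated at 0.972 (sample 231) to 0.982 (sample 240). NPRA-/- sample 240 correlated at 0.973 (sample 230) to 0.985 (sample 242) with the NPRA+/+ samples. With the other NPRA-/- samples it correlated at 0.951 (sample 217, the lowest value within NPRA-/-) to 0.982 (sample 227), so these ranges overlapped. The highest value within NPRA-/- was 0.990, and the pairs of NPRA+/+ samples ranged from 0.985 to 0.988.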
